A study of Mus musculus with 24 samples.

How the data were processed

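The series holds RNA sequencing of dendritic cells (DCs) grown from mouse bone marrow. Per the labels, the cells were wild type (WT) or knockout (KO) for IRE1α, the endoplasmic reticulum (ER) stress sensor encoded by Ern1, and were left untreated, treated with zymosan or treated with lipopolysaccharide (LPS). The 6 groups had 4 replicates each, 24 samples in total. RNA was isolated with a column kit for small amounts, its quality was checked on a Bioanalyzer, and mRNA libraries were sequenced, per the labels. The labels do not say whether replicates were separate mice, separate cultures or repeated libraries, so the p-values below measure the spread between these samples, part of which may be technical.

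The deposited table gives 1 whole-number count per gene and sample, for 38887 Ensembl genes. Per the submitters' processing notes, Bowtie2, RSEM 1.2.31 and DESeq2 were used with the mouse genome build mm10. The notes do not give the role or order of each tool. The plan written before the data were examined assumed RSEM expected counts with decimals, to be rounded. The deposited counts were already whole numbers and were used unchanged. Reads that map to several genes are shared out by RSEM, so counts of near-identical gene copies are less certain than those of single genes. Counts cover a whole gene, so neither the spliced form of Xbp1 nor single exons of Ern1 can be read from them. Gene names and positions came from GENCODE M21 (GRCm38), which named 37570 of the gene identifiers (96.6%).

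The total count per sample was 32223256 to 46927434. Of the 38887 genes, 14809 had no count in any sample and 14188 passed edgeR's filterByExpr with the 6 groups. Normalization factors by the trimmed mean of M values (TMM) were 0.880 to 1.19, and the common biological coefficient of variation was 0.0686. Levels are given as CPM (counts relative to the library total scaled by these factors), as means ± SD of 4 samples; log2 CPM used a prior count of 2.

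One edgeR quasi-likelihood model with a mean per group was fitted to all 24 samples (edgeR 4.0.16, R 4.3.3). Tests were 3 contrasts in WT cells (zymosan against untreated, LPS against untreated, zymosan against LPS), 3 of KO against WT within each condition, the same stimulation contrasts against untreated cells in KO, and the 2 interactions, which test whether the log2 response to zymosan or to LPS differed between genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison; "edgeR adjusted p" below means this value. Fold changes are log2 values ± standard error (SE) from the model with n = 4 samples per group. Intervals of ratios for genes with very low counts cover counting error only.

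Before the data were examined, 26 lists of pathways and cell type markers (379 genes, 351 of them tested) were fixed, as were the comparisons, thresholds and the rule for which genes are named. For each list the text gives the number of members called over all genes and, where it says so, the number called when p-values were adjusted over the list alone. The lists were also tested with camera on voom weights (limma 3.58.1) with the preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over lists and comparisons; the same test with a correlation estimated from the data is given where it changes the call. In all, 25 lists had enough measured members to be tested.

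Named genes are Ern1 and Xbp1; the prostaglandin genes Ptgs2, Ptges, Ptgs1, Pla2g4a, Ptges2 and Ptges3; up to 2 called members of each pathway list, and 1 of each marker list, with the largest change; and the 5 largest rises and falls among called genes with a mean of at least 5 CPM and no overlap between the samples of both groups (in the interactions, by adjusted p and CPM only). Predicted genes without a given name were left out, and not every gene the rule allows is printed. Any other gene is said to have been chosen after its values were seen.

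Alternatives fixed beforehand were DESeq2 1.42.0 as the test, its size-factor scaling, no filter on low counts, a model of only the groups compared, replicate number as a block (shared by both genotypes or nested in genotype), and leaving out each library in turn. Further alternatives, chosen after seeing the data, were the counts of replicates 1 and 2 and of replicates 3 and 4 summed within each group (2 sums per group), each of these pairs of replicates alone, and a model term for the pairs. Each comparison was also repeated over splits of its own samples into other groups, the real one included: all 35 splits of 8 samples, or 100 splits of 16 samples for an interaction.

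The procedure was tested on simulated data that kept each gene's observed mean and dispersion and treated all replicates as independent, with 13933 tested genes. Changes were planted only in genes with an expected count of at least 50 in a library of mean size. The rates below therefore do not cover genes of fewer counts. Nor do they cover replicates that resemble each other in pairs, as described below for these samples. For KO zymosan against WT zymosan the procedure recovered 72% of 50 planted changes of 5/4-fold, 94% of 1.5-fold and 100% of 2-fold and 4-fold changes, with 8 false calls. For the zymosan interaction it recovered 44%, 82%, 96% and 100%, with 10 false calls. With nothing planted in KO LPS against WT LPS, 0 genes were called. Protein, lipid and secreted prostaglandin levels, read sequences and transcript forms were not analysed here.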

Results

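The series title concerns IRE1α-XBP1 signalling in leukocytes, prostaglandin synthesis and pain. IRE1α is an ER membrane sensor whose RNase splices Xbp1 mRNA, and the spliced product encodes the transcription factor XBP1s. Zymosan, a yeast cell wall preparation, is sensed by dectin-1 and Toll-like receptors, and LPS by Toll-like receptor 4. The questions were which genes DCs change in answer to each stimulus, which differ between genotypes, and whether the response itself differs by genotype. On the first principal component of log2 CPM (68.4% of variance), untreated samples lay apart from stimulated ones, and on the second (7.60%) the genotype labels lay apart.

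Ern1 (ENSMUSG00000020715, chromosome 11, 106394650 to 106487852, minus strand) was measured first, as the gene named in the genotype label. Its mRNA was not lower in the libraries labelled KO. In untreated cells its level was 40.2 to 43.3 CPM in the 4 WT samples and 48.2 to 54.6 CPM in the 4 samples labelled KO. The ranges were 29.5 to 30.7 and 35.6 to 39.2 CPM with zymosan, and 27.1 to 29.9 and 36.6 to 41.8 CPM with LPS. The log2 difference, labelled KO over WT, was 0.31 ± 0.05 in untreated cells, 0.31 ± 0.05 with zymosan and 0.47 ± 0.05 with LPS (SE, n = 4 per group, edgeR adjusted p = 6.99e-05, 6.48e-05 and 1.43e-07). With replicate pairs summed, a setting described below, the untreated call ended (edgeR adjusted p = 0.0566). A count over the whole gene includes exons that a conditional allele leaves in place, so it checks nothing about the deletion, and samples are called labelled KO throughout. Xbp1 (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893, plus strand) had log2 differences of 0.08, -0.09 and 0.00, none of which passed; these totals do not separate spliced from unspliced transcripts.

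**Figure D1:**
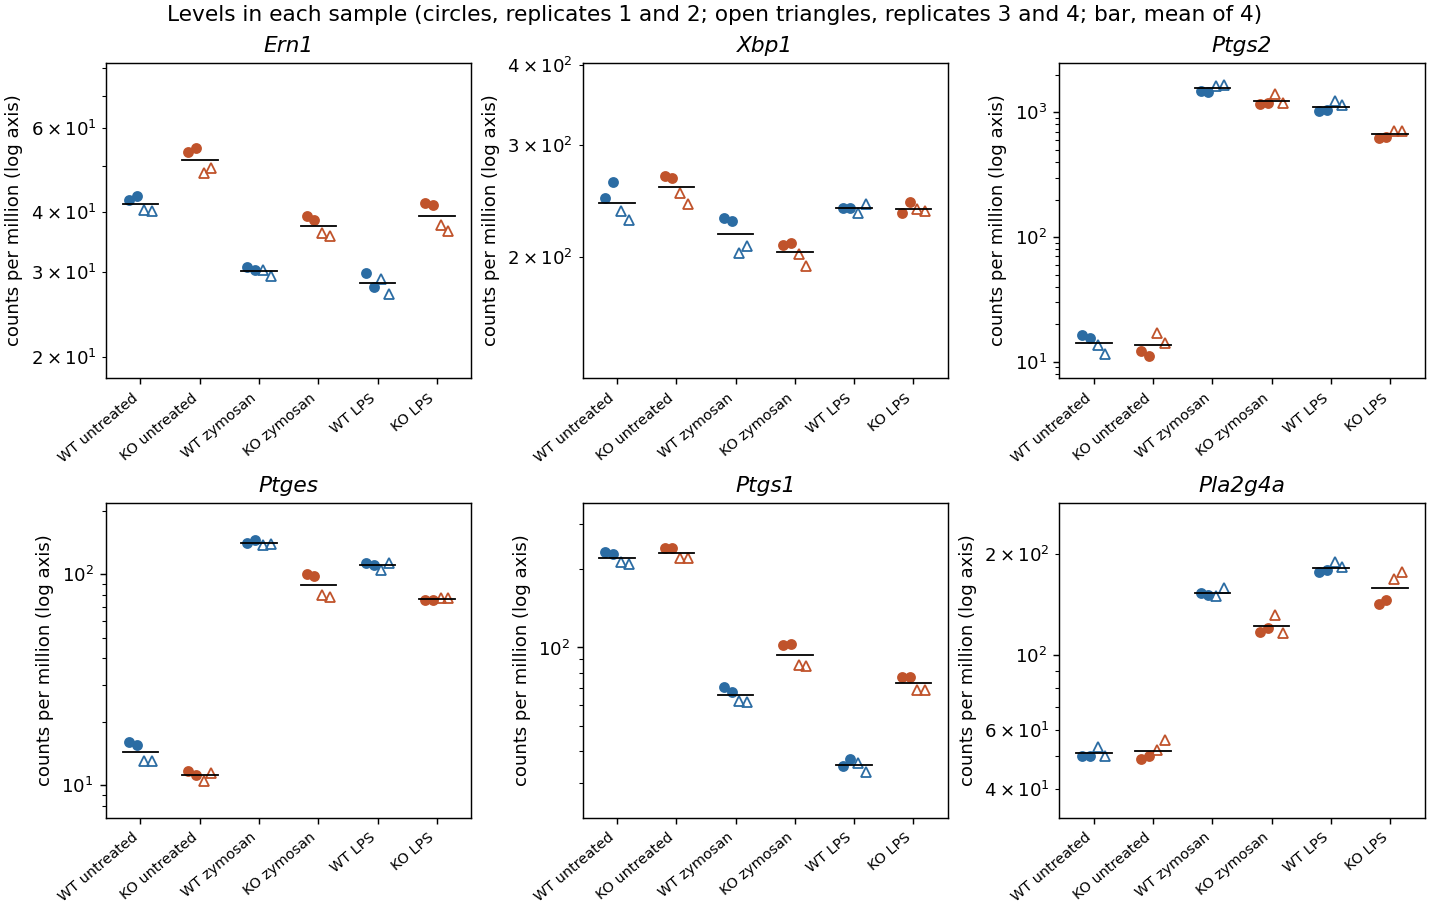
Levels of Ern1, Xbp1 and the prostaglandin genes Ptgs2, Ptges, Ptgs1 and Pla2g4a in each sample, in TMM-scaled CPM on a log axis, for the 6 groups of genotype label and stimulus. Filled circles are replicates 1 and 2, open triangles replicates 3 and 4, and bars are group means of 4 samples.

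In all groups but WT LPS, replicates 1 and 2 resembled each other, and replicates 3 and 4 each other, more than either resembled the rest. In WT LPS this held for replicates 1 and 2, while replicate 3 lay nearer to replicate 2 than to replicate 4 (chi-square per gene 7.24 and 8.24). The chi-square per gene between a pair of libraries, near 1 for counting noise alone, was 1.91 to 8.24 (median 4.23) in these 12 pairs and 7.24 to 23.8 (median 16.8) in the other 24. Each comparison was therefore repeated with the counts of replicates 1 and 2, and of 3 and 4, summed within each group, a setting chosen after seeing the data. Its values are given, at the value or later in the text on the same comparison, for a named gene whose call it ends, a total it moves by more than 1.5 times, and a list in which it moves the larger of the counts higher and lower by as much.

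Zymosan in WT cells, the first question, raised Ptgs2, Ptges and Pla2g4a, which act in prostaglandin synthesis, and inflammatory cytokines. Ptgs2 (cyclooxygenase 2, the inducible enzyme that makes prostaglandin H2, ENSMUSG00000032487, chromosome 1, 150100031 to 150108227, plus strand) rose from 14.2 ± 2.12 to 1557 ± 99.4 CPM, a log2 fold change of 6.78 ± 0.13 or 109.5-fold (n = 4 per group, edgeR adjusted p = 2.64e-23). Ptges, the microsomal prostaglandin E synthase that acts after it (ENSMUSG00000050737, chromosome 2, 30889471 to 30929863, minus strand), rose 9.77-fold, and Pla2g4a, the cytosolic phospholipase that frees arachidonic acid (ENSMUSG00000056220, chromosome 1, 149829618 to 149961290, minus strand), 3.00-fold. Ptgs1, the constitutive cyclooxygenase (ENSMUSG00000047250, chromosome 2, 36230426 to 36252272, plus strand), was 3.37-fold lower, falling from 221 ± 11.4 to 65.6 ± 4.21 CPM. The other E synthases, Ptges2 and Ptges3, had log2 values of 0.12 ± 0.07 and 0.12 ± 0.05 and did not pass (edgeR adjusted p = 0.129 and 0.0504). Ptges2 passed without WT untreated replicate 4 (0.0428) or WT zymosan replicate 3 (0.0443), and Ptges3 without WT untreated replicate 3 (0.0373) or WT zymosan replicate 2 (0.0131) and with DESeq2 (0.0375).

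All 20 measured cytokines rose with zymosan (median log2 fold change 3.48, camera adjusted p = 3.23e-13), among them Il12b (269.7-fold), the p40 subunit of interleukin 12 and 23, and Il6 (121-fold). Il10, an anti-inflammatory cytokine, had 3 counts in all WT untreated samples together, and its ratio by counts was 914 (95% interval 312 to 4434). All 24 measured interferon-stimulated genes rose too (median 4.39, for example Oasl1 6.73 ± 0.18 and Rsad2 6.36 ± 0.26, camera adjusted p = 2.82e-17). So did 18 of 19 chemokines (Cxcl10 7.06 ± 0.25, camera adjusted p = 2.04e-09) and 16 of 17 genes of DC maturation and antigen presentation, or 17 adjusted over the list alone, such as the co-stimulatory receptor Cd40 (5.19 ± 0.10, camera adjusted p = 7.91e-09). With an estimated correlation these 3 list calls were lost, with adjusted p = 0.161, 0.107 and 0.116. All 17 NF-κB targets and feedback genes rose, among them Nfkbiz (3.30 ± 0.07) and the cytokine signalling inhibitor Socs3 (2.73 ± 0.05), and that list kept its call (camera adjusted p = 3.51e-13, and 0.0275 with an estimated correlation).

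Among proliferation genes 16 of 18 fell with zymosan and 1 rose (Plk1, a mitotic kinase, -1.68 ± 0.13; Mcm2, a replication licensing factor, -1.60 ± 0.08, camera adjusted p = 4.34e-07, and adjusted p = 0.156 with an estimated correlation). Of 21 genes of glycolysis and hypoxia 15 rose and 2 fell (Hif1a 1.89 ± 0.06, Pfkfb3 1.66 ± 0.07, camera adjusted p = 0.000741, and adjusted p = 0.442 with an estimated correlation). The sterol synthesis enzyme Dhcr7 fell (-2.61 ± 0.09) and so did fatty acid synthase, Fasn (-1.52 ± 0.07), while 6 of the 20 genes of that list rose and 10 fell (camera adjusted p = 0.258). Of the 38 XBP1s targets 17 rose and 8 fell (median 0.07, camera adjusted p = 0.165). The chaperone Hspa5, also called BiP, rose (0.96 ± 0.07) within a list of ER chaperones with 5 rises and 2 falls of 13 (camera adjusted p = 0.592). Over the 12 measured genes of prostanoid synthesis and transport 3 rose and 5 fell (5 and 5 adjusted over the list alone). Their median was -0.07, their mean 0.52, and the list test gave an adjusted p = 0.999 by camera. In all, 4867 genes were higher and 5091 lower by edgeR, of which 1384 and 1243 by more than 2-fold. Xbp1 was lower by -0.16 ± 0.05 (edgeR adjusted p = 0.00322), a call that ended with summed pairs (edgeR adjusted p = 0.0924).

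LPS in WT cells also raised Ptgs2, Ptges and Pla2g4a and lowered Ptgs1. Ptgs2 rose 78.3-fold (log2 6.29 ± 0.13) to 1113 ± 94.4 CPM, Ptges 7.68-fold (2.94 ± 0.08) and Pla2g4a 3.58-fold (1.84 ± 0.06), and Ptgs1 was 6.28-fold lower (-2.65 ± 0.07), with edgeR adjusted p of 1.82e-19 or less for each (n = 4 per group). Ptges2 rose (0.62 ± 0.07). Il12b rose 1091-fold (10.09 ± 0.12) to a mean of 2864 CPM, Cd40 98.1-fold (6.62 ± 0.10), and the T cell attractants Cxcl9 and Cxcl10 by 8.68 ± 0.19 and 8.49 ± 0.26. Il10 had a ratio by counts of 935 (95% interval 319.6 to 4539).

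Again all 20 cytokines, all 24 interferon-stimulated genes, all 17 genes of DC maturation and all 17 NF-κB genes rose with LPS, with medians of 2.90, 5.38, 1.22 and 1.55 (camera adjusted p = 9.61e-11, 1.02e-15, 8.81e-09 and 3.32e-11). With an estimated correlation the NF-κB list kept its call (adjusted p = 0.0363) and the others did not (adjusted p = 0.0545, 0.179 and 0.116 in that order). Of 19 chemokines 18 rose and 1 fell (camera adjusted p = 8.82e-08, and adjusted p = 0.134 with an estimated correlation). Proliferation genes fell in 17 of 18 cases (cyclin genes Ccna2 -2.05 ± 0.09 and Ccnb1 -2.01 ± 0.09, camera adjusted p = 1.14e-06, and adjusted p = 0.161 with an estimated correlation). Of 20 genes of cholesterol and fatty acid synthesis 13 fell and 3 rose (Dhcr7 -3.06 ± 0.10, Fasn -1.97 ± 0.07, camera adjusted p = 0.0114, and adjusted p = 0.345 with an estimated correlation). Falls were also large in the adhesion gene Cdh1, encoding E-cadherin (-4.20 ± 0.07), the tropomyosin gene Tpm2 (-4.31 ± 0.21) and Fam198b (-4.47 ± 0.13). Hspa5 (1.17 ± 0.07) and the ER-stress-inducible factor Manf (0.71 ± 0.06) rose, and of the 38 XBP1s targets 20 rose and 8 fell (camera adjusted p = 0.0953). Of the 12 prostanoid genes 5 rose and 6 fell (camera adjusted p = 0.942). In all, 5100 genes were higher and 5629 lower by edgeR, 1766 and 1953 of them by more than 2-fold.

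Zymosan and LPS were compared directly in WT cells. Ptgs2 was 1.40-fold higher with zymosan (log2 0.49 ± 0.10, edgeR adjusted p = 0.000208, n = 4 per group), as were Ptges (0.35 ± 0.07) and Ptgs1 (0.90 ± 0.07). Pla2g4a (-0.25 ± 0.06) and Ptges2 (-0.50 ± 0.07) were lower. Csf3, the granulocyte colony-stimulating factor, was 5.02-fold higher with zymosan, the neutrophil attractant Cxcl1 was higher by 1.70 ± 0.11 and the immediate early gene Egr3 by 2.03 ± 0.14. Il12b was 4.05-fold and Cxcl9 4.10-fold lower with zymosan than with LPS, and Thbs4, a thrombospondin, 6.09-fold lower.

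Interferon-stimulated genes were lower with zymosan than with LPS in 23 of 24 cases, 24 adjusted over the list alone (Cmpk2 -1.59 ± 0.20, Ifit3 -1.24 ± 0.20; median -0.87, camera adjusted p = 7.21e-12, and adjusted p = 0.294 with an estimated correlation). Of 17 genes of DC maturation 12 were lower and 1 higher, with Cd40 at -1.42 ± 0.08 and the interleukin 15 receptor gene Il15ra at -1.08 ± 0.06 (camera adjusted p = 3.15e-05, and adjusted p = 0.241 with an estimated correlation). With summed pairs 7 were lower and 0 higher. Immediate early genes were higher in 11 of 16 cases and lower in 1 (median 0.60, camera adjusted p = 5.06e-05, and 0.0455 with an estimated correlation). Genes of cholesterol and fatty acid synthesis were higher in 16 of 20 (Scd2 0.73 ± 0.06, camera adjusted p = 2.3e-06, and adjusted p = 0.0824 with an estimated correlation). Those of glycolysis and hypoxia were higher in 15 of 21 cases and lower in 1 (Gpi1 0.69 ± 0.07, camera adjusted p = 8.22e-05, and adjusted p = 0.352 with an estimated correlation). Cytokines went both ways, with 9 higher and 6 lower of 20 (camera adjusted p = 0.721). By edgeR 3481 genes were higher and 3106 lower with zymosan; with summed pairs the numbers were 2280 and 1979.

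Labelled KO was compared with WT in untreated cells, the second question. Genes of ER translocation, folding and degradation that XBP1s is known to drive were lower. The co-chaperone Dnajb9 (ENSMUSG00000014905, chromosome 12, 44205559 to 44210326) was 2.73-fold lower, from 24.5 to 8.98 CPM (log2 -1.45 ± 0.08, n = 4 per group). The COPII coat gene Sec24d was 3.19-fold lower (-1.67 ± 0.09), and the ER chaperone Hyou1 and the ER-stress gene Creld2 had -0.93 ± 0.05 and -0.93 ± 0.04 (edgeR adjusted p of 3.23e-12 or less for each). Of the 38 XBP1s targets 35 fell and none rose, with a median of -0.47 (camera adjusted p = 9.06e-60, and 0.000456 with an estimated correlation); adjusted over the list alone 36 were lower and 1 higher. Of 13 ER chaperones 7 fell (8 adjusted over the list alone, camera adjusted p = 4.85e-12, and 0.0275 with an estimated correlation). Of 18 PERK-ATF4 targets 8 rose (12 adjusted over the list alone) and none fell, among them Asns, asparagine synthetase (1.14 ± 0.07, 2.21-fold), and the serine synthesis enzyme Phgdh (0.77 ± 0.09, camera adjusted p = 2.09e-11, and 0.00319 with an estimated correlation).

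The largest falls were in eosinophil granule genes. Epx, eosinophil peroxidase (ENSMUSG00000052234, chromosome 11, 87864000 to 87875536, minus strand), went from 187 ± 29.9 CPM to 0.755 ± 0.107 CPM in samples labelled KO, 249-fold lower (log2 -7.96 ± 0.16, edgeR adjusted p = 5.51e-22). Prg2, the major basic protein (ENSMUSG00000027073, chromosome 2, 84980461 to 84983632), was 114-fold lower and Alox15, a lipoxygenase also known from eosinophils and macrophages, 11.2-fold lower. Ear1, a ribonuclease gene of a family of near copies (ENSMUSG00000072601, chromosome 14, 43818765 to 43875517), had a log2 value of -8.67 ± 0.14. In the marker list of mast cells, basophils and eosinophils 4 of 8 fell (camera adjusted p = 8.63e-07, and adjusted p = 0.161 with an estimated correlation). In the neutrophil list 4 of 11 fell and 1 rose (camera adjusted p = 0.163; 1 and 0 with summed pairs), with Ly6g at -1.88 ± 0.19. Eosinophil genes and XBP1s targets were both lower in all 3 conditions. Flt3, a growth factor receptor of DC precursors, was lower (-1.14 ± 0.13), while the list of conventional DC markers that holds it gave no list call. Fscn1, an actin bundler of mature DCs, was lower too (-0.71 ± 0.07). In the list of DC maturation and antigen presentation, which holds Fscn1, 7 of 17 were higher and 1 lower (camera adjusted p = 0.00211, and adjusted p = 0.437 with an estimated correlation). Of 4 stroma markers 1 was higher, or 4 adjusted over the list alone (median 0.81, camera adjusted p = 0.0178, and adjusted p = 0.34 with an estimated correlation). Plasmacytoid DC markers were higher in 2 of 4 cases (median 0.26, camera adjusted p = 0.0187, and adjusted p = 0.17 with an estimated correlation). The antigen presentation gene H2-Aa (0.39 ± 0.05), Timp3 (1.48 ± 0.10) and Stfa1 (1.48 ± 0.15) were higher.

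**Figure D2:**
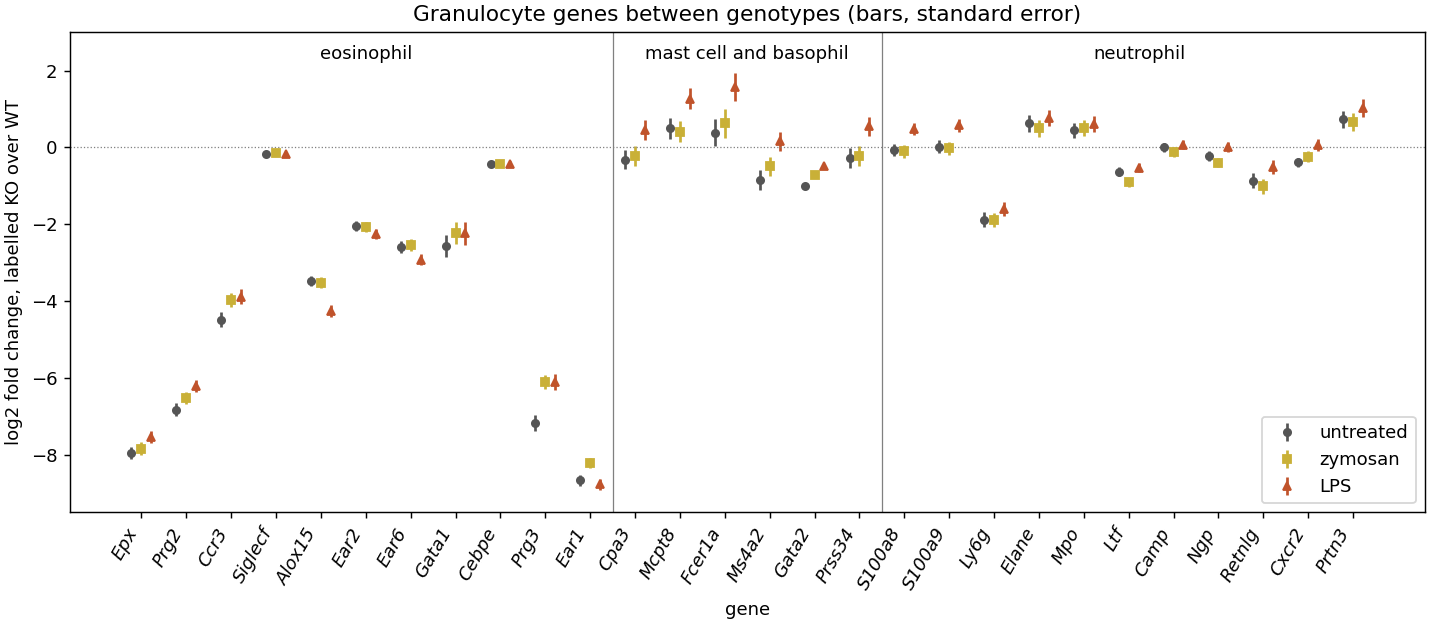
Log2 fold change, labelled KO over WT, of genes known from eosinophils, from mast cells and basophils, and from neutrophils, in untreated, zymosan-treated and LPS-treated cells (n = 4 per group). Points are estimates of the edgeR model and bars are ± 1 SE. Eosinophil genes other than Epx, Prg2, Prg3, Ear1 and Alox15 were chosen after the fall of Epx was seen. The mast cell and basophil genes were members of a marker list fixed beforehand, and were set apart from its eosinophil genes afterwards.

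In untreated cells most prostaglandin genes did not pass between genotype labels: Ptgs2 had -0.06 ± 0.11, Ptgs1 0.06 ± 0.06 and Pla2g4a 0.02 ± 0.06. Ptges was lower (-0.36 ± 0.08, edgeR adjusted p = 0.00268), a call that ended with summed pairs (edgeR adjusted p = 0.164). Ptgs2 differed by replicate pair, at -0.44 (edgeR adjusted p = 2.15e-05) with replicates 1 and 2 alone and 0.31 (0.0786) with replicates 3 and 4, and its sign turned without WT untreated replicate 1 or KO untreated replicate 2, as did that of Pla2g4a without KO untreated replicate 4. Cytokines (1 higher and 3 lower of 20), chemokines (1 and 5 of 19) and NF-κB genes (0 and 1 of 17) gave no list call (camera adjusted p = 0.616, 0.0774 and 0.923), and with summed pairs 0, 1 and 0 of them were lower. Genes of cholesterol and fatty acid synthesis were lower in 4 of 20 cases, 1 with summed pairs, and higher in none (camera adjusted p = 6.24e-05, and adjusted p = 0.132 with an estimated correlation). By edgeR 611 genes were higher and 800 lower in samples labelled KO, 45 and 110 of them by more than 2-fold. With summed pairs the numbers were 118 and 300.

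**Figure D3:**
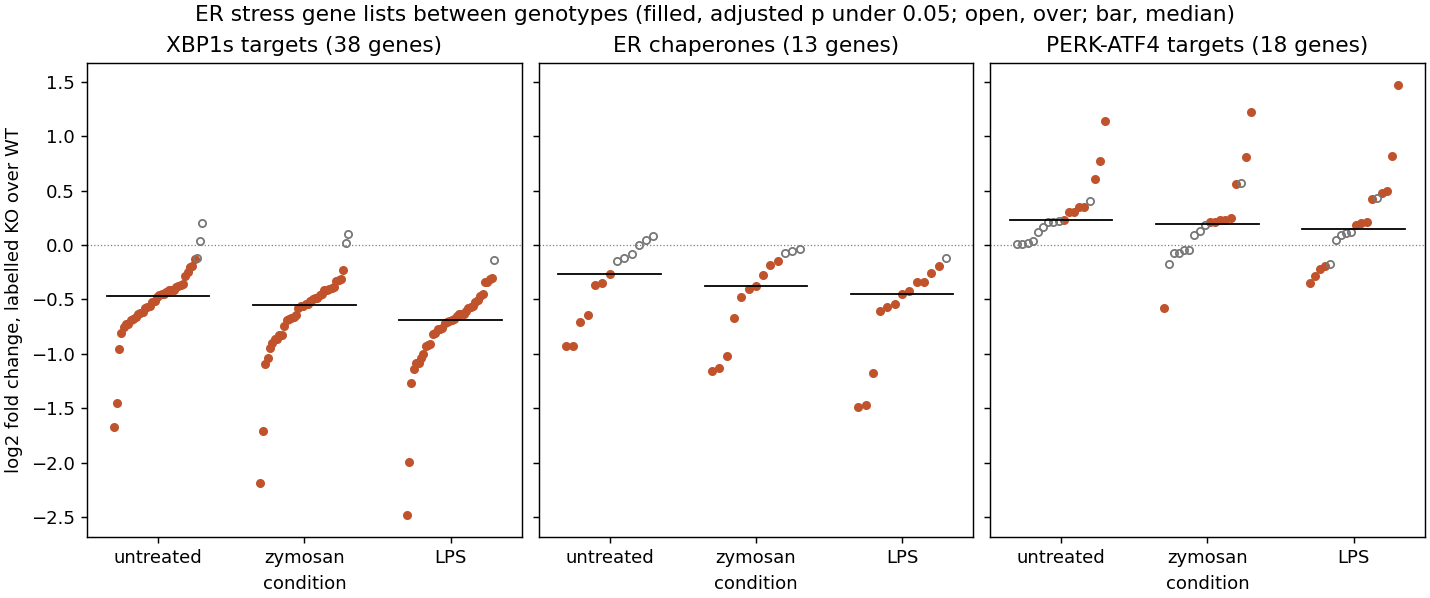
Log2 fold change, labelled KO over WT, of each member of the lists of XBP1s targets (38 genes), ER chaperones (13) and PERK-ATF4 targets (18) in untreated, zymosan-treated and LPS-treated cells (n = 4 per group). Each point is a gene, filled where its edgeR adjusted p was under 0.05, and the bar is the list's median.

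With zymosan, samples labelled KO had less mRNA of the inducible prostaglandin enzymes than WT and more Ptgs1. Ptges was 1.58-fold lower (89.0 ± 11.6 against 141 ± 3.59 CPM; log2 -0.66 ± 0.07, edgeR adjusted p = 6.7e-08, n = 4 per group), Pla2g4a was lower (-0.33 ± 0.06; 0.000116) and Ptgs1 was 1.43-fold higher (0.52 ± 0.07; 1.81e-06). Ptgs2 was also lower (1241 ± 115 against 1557 ± 99.4 CPM; -0.33 ± 0.10, edgeR adjusted p = 0.0166), a call that ended with summed pairs (0.205) and without WT zymosan replicate 4 (0.0512), KO zymosan replicate 1 (0.0543) or KO zymosan replicate 2 (0.0538). Over the 12 prostanoid genes 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (median -0.03, camera adjusted p = 0.716).

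Dnajb9 was 4.55-fold lower with zymosan in samples labelled KO (-2.19 ± 0.09), Sec24d lower by -1.71 ± 0.10 and Creb3l2, an ER-resident transcription factor gene, 16.6-fold lower (-4.05 ± 0.12). Of the 38 XBP1s targets 36 fell (median -0.55, camera adjusted p = 3.52e-50, and 0.000723 with an estimated correlation). Of the 13 ER chaperones 10 fell (Creld2 -1.16 ± 0.04, Hyou1 -1.13 ± 0.05, camera adjusted p = 6.17e-13, and 0.0244 with an estimated correlation). PERK-ATF4 targets rose in 8 of 18 cases and 1 fell (Asns 1.23 ± 0.07, camera adjusted p = 0.0039, and adjusted p = 0.147 with an estimated correlation). With summed pairs 3 rose.

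Cytokines were lower in 11 of 20 cases and none were higher (Il10 -0.94 ± 0.10, the inflammasome product gene Il18 -0.95 ± 0.12, camera adjusted p = 8.48e-08, and adjusted p = 0.108 with an estimated correlation). Of 19 chemokines 11 were lower and 1 higher (Cxcl9 -0.99 ± 0.12, Ccl24 -0.96 ± 0.08, camera adjusted p = 9.87e-06, and adjusted p = 0.186 with an estimated correlation). NF-κB genes were lower in 10 of 17 cases (Traf1 -0.34 ± 0.05, camera adjusted p = 1.23e-05, and adjusted p = 0.147 with an estimated correlation). Receptors and adaptors for zymosan and LPS were lower in 8 of 16 and higher in 1, with the LPS co-receptor Cd14 at -0.83 ± 0.07 and Tlr2 at -0.65 ± 0.07 (camera adjusted p = 0.00165, and adjusted p = 0.16 with an estimated correlation). Adjusted over each list alone, 12 cytokines, 12 chemokines, 11 NF-κB genes and 9 receptors were lower. Proliferation genes were higher in 13 of 18 (Plk1 0.73 ± 0.13, Ccnb1 0.53 ± 0.09, camera adjusted p = 5.55e-09, and adjusted p = 0.114 with an estimated correlation). With summed pairs 3 chemokines, 5 NF-κB genes and 3 receptors were lower and 7 proliferation genes higher. The eosinophil genes were low here too, with Epx 229-fold and Prg2 91.8-fold lower. By edgeR 1510 genes were higher and 1624 lower, 72 and 151 of them by more than 2-fold; with summed pairs the numbers were 394 and 570.

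With LPS, samples labelled KO had less mRNA of Ptgs2 and Ptges than WT and more Ptgs1. Ptgs2 was 1.66-fold lower in samples labelled KO (672 ± 46.1 against 1113 ± 94.4 CPM; log2 -0.73 ± 0.10, edgeR adjusted p = 3.14e-06, n = 4 per group), Ptges 1.45-fold lower (-0.53 ± 0.07; 1.44e-06) and Ptgs1 2.07-fold higher (1.05 ± 0.07; 1.11e-11). Pla2g4a was lower (-0.20 ± 0.06, edgeR adjusted p = 0.00705), a call that ended with summed pairs (0.131). Of the 12 prostanoid genes 2 rose and 4 fell (median -0.12, camera adjusted p = 0.443; 1 and 2 with summed pairs). Dnajb9 was 5.59-fold lower (-2.48 ± 0.09), Sec24d 3.98-fold, Hyou1 2.80-fold and Creld2 2.77-fold lower, and Asns 2.78-fold higher. Of the 38 XBP1s targets 37 fell (median -0.69, camera adjusted p = 4.2e-47, and 0.000758 with an estimated correlation), 38 adjusted over the list alone. ER chaperones fell in 12 of 13 cases (camera adjusted p = 1.83e-14, and 0.0184 with an estimated correlation). Of the 18 PERK-ATF4 targets 8 rose and 4 fell (camera adjusted p = 0.015, and adjusted p = 0.186 with an estimated correlation), and with summed pairs 5 and 1.

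Il10 was 2.74-fold lower with LPS in samples labelled KO (-1.46 ± 0.10), Csf3 lower by -0.98 ± 0.13, the monocyte attractant Ccl12 3.29-fold and Cxcl9 3.15-fold lower. In the lists, 14 of 20 cytokines, 16 of 19 chemokines and 14 of 17 NF-κB genes fell (Tnfaip3, a deubiquitinase that restrains NF-κB, -0.51 ± 0.05), with 1, 1 and 0 rising (camera adjusted p = 1.46e-08, 5.89e-08 and 1.6e-08 and adjusted p = 0.094, 0.133 and 0.0792 with an estimated correlation). Interferon-stimulated genes fell in 17 of 24 cases (median -0.51, camera adjusted p = 5.63e-07, and adjusted p = 0.489 with an estimated correlation); with summed pairs 3 were called. Macrophage and monocyte markers fell in 9 of 10 cases and 1 rose (the complement gene C1qa -0.88 ± 0.09, camera adjusted p = 7.36e-06, and adjusted p = 0.16 with an estimated correlation). Genes of cholesterol and fatty acid synthesis were higher in 14 of 20 cases and lower in 1, with Scd2 at 0.50 ± 0.06 and Dhcr7 at 0.56 ± 0.12 (camera adjusted p = 2e-05, and adjusted p = 0.11 with an estimated correlation). Proliferation genes were higher in 15 of 18 and lower in 1, with Ccnb1 at 0.81 ± 0.10 and the spindle checkpoint kinase Bub1 at 0.78 ± 0.08 (camera adjusted p = 5.18e-06, and adjusted p = 0.179 with an estimated correlation). Adjusted over each list alone, 15 cytokines, 16 chemokines, 15 NF-κB genes and 18 interferon-stimulated genes were lower and 15 sterol genes and 15 proliferation genes higher. With summed pairs 8 NF-κB genes were lower and 7 sterol genes higher. Epx was 186-fold and Prg2 74.5-fold lower. By edgeR 2220 genes were higher and 2585 lower, 146 and 196 of them by more than 2-fold; with summed pairs the numbers were 841 and 1146.

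**Figure D4:**
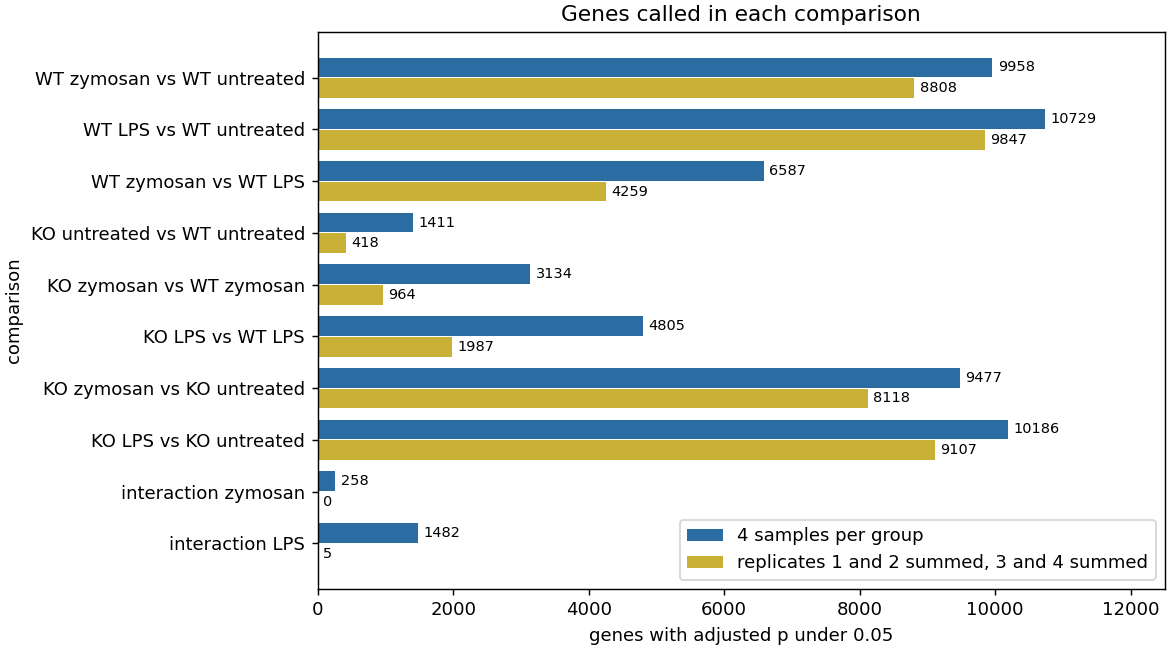
Number of genes called at an edgeR adjusted p under 0.05 in each comparison, with 4 samples per group and with the counts of replicates 1 and 2 and of replicates 3 and 4 summed (2 sums per group).

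Some genes differed between the genotype labels in all 3 conditions. Of the genes tested 264 were higher and 510 lower in samples labelled KO each time, and 6 were called each time with mixed direction. Commd10 (ENSMUSG00000042705, chromosome 18, 46958816 to 47234284), which takes part in endosomal sorting, was 3.24-fold higher with LPS (1.70 ± 0.05, edgeR adjusted p = 6.04e-19). Its values in the other conditions, looked up after this one was seen, were 0.40 ± 0.04 untreated and 1.11 ± 0.05 with zymosan. Clec4f, a lectin known from liver macrophages (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187, minus strand), had 0 counts in WT zymosan and 1809 in the 4 samples labelled KO, at least 639.7-fold more against a floor of 3 counts over the WT group, and 1 against 2408 counts with LPS. In untreated cells, also looked up afterwards, the counts were 0 and 334.

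Stimulation was also tested within samples labelled KO. With zymosan Ptgs2 rose 91.2-fold (6.51 ± 0.13), Ptges 7.92-fold (2.99 ± 0.08) and Pla2g4a 2.35-fold (1.23 ± 0.06), and Ptgs1 was 2.46-fold lower (-1.30 ± 0.07; n = 4 per group, edgeR adjusted p of 4.83e-15 or less for each). With LPS the values were 49.4-fold (5.63 ± 0.12), 6.80-fold (2.77 ± 0.08), 3.06-fold (1.61 ± 0.06) and 3.17-fold lower (-1.66 ± 0.07). Il12b rose by 7.93 ± 0.11 and 9.82 ± 0.12 and Cd40 by 4.81 ± 0.10 and 5.98 ± 0.10. All 20 cytokines, all 24 interferon-stimulated genes and all 17 NF-κB genes rose with each stimulus (camera adjusted p = 3.01e-14, 9.74e-20 and 2.6e-14 with zymosan, and 5.36e-11, 2.82e-17 and 3.32e-11 with LPS). With an estimated correlation the cytokine list was lost with LPS (adjusted p = 0.0528) and the interferon list with both (adjusted p = 0.147 and 0.161). Proliferation genes fell in 16 and 17 of 18 cases (camera adjusted p = 1.69e-06 and 5.63e-07 and adjusted p = 0.162 and 0.158 with an estimated correlation). Of the XBP1s targets 12 rose and 14 fell with zymosan, and 13 rose and 20 fell with LPS (camera adjusted p = 0.965 and 0.535); with summed pairs 10 rose and 8 fell with zymosan. By edgeR 4487 genes were higher and 4990 lower with zymosan, and 4886 and 5300 with LPS.

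Whether the response to zymosan differed by genotype label, the third question, was tested as an interaction. Ptgs1 fell less in samples labelled KO than in WT (difference of log2 responses 0.46 ± 0.09, edgeR adjusted p = 0.00866, n = 4 per group), and Pla2g4a rose less (-0.36 ± 0.08; 0.0209; without KO zymosan replicate 1 0.0534, without KO zymosan replicate 2 0.0521). Ptgs2 (-0.26 ± 0.15, edgeR adjusted p = 0.492) and Ptges (-0.30 ± 0.10; 0.147) did not pass, but did with replicates 3 and 4 alone (0.0236 and 0.00373). With replicates 1 and 2 alone the sign of Ptgs2 turned. Dnajb9 had -0.74 ± 0.12, Socs3 -0.43 ± 0.07, the phosphatase Dusp1 -0.56 ± 0.11, Pfkfb3 -0.55 ± 0.10, the retinoic acid hydroxylase Cyp26b1 -0.80 ± 0.12 and Commd10 0.71 ± 0.06, all called. Called lower were 2 of 38 XBP1s targets (camera adjusted p = 4.43e-08, and adjusted p = 0.147 with an estimated correlation), 3 of 17 NF-κB genes (1.78e-08 and 0.0792) and 1 of 20 cytokines (1.64e-05 and 0.161). Called higher were 4 of 18 proliferation genes (camera adjusted p = 3.38e-11, and adjusted p = 0.0797 with an estimated correlation). Adjusted over each list alone, the counts were 9, 8, 7 and 11. By edgeR 138 genes were higher and 120 lower, with 1855 under an unadjusted p of 0.05; a replicate block nested in genotype gave 292 and 298, and DESeq2 228 and 196. With summed pairs edgeR called 0 and 0, ending every call named for this interaction. Leaving out KO zymosan replicate 2 gave 69 and 56, KO zymosan replicate 1 gave 91 and 63, and WT zymosan replicate 2 gave 78 lower.

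The response to LPS was tested for a difference by genotype label in the same way. Ptgs2 rose less in samples labelled KO (difference of log2 responses -0.67 ± 0.15, edgeR adjusted p = 0.0054, n = 4 per group; summed pairs 0.254) and Ptgs1 fell less (0.99 ± 0.09; 5.81e-07; summed pairs 0.0534), while Ptges had -0.17 ± 0.10 and did not pass (0.302). Dnajb9 (-1.03 ± 0.12), Hyou1 (-0.56 ± 0.07) and Creld2 (-0.55 ± 0.06) were lower relative to WT. Also lower were 25 of the 38 XBP1s targets, 32 adjusted over the list alone (camera adjusted p = 9.14e-18, and 0.0315 with an estimated correlation). Of 13 ER chaperones 9 were lower (camera adjusted p = 7.91e-09, and adjusted p = 0.055 with an estimated correlation). Of NF-κB genes 11 of 17 were lower (Tnfaip3 -0.50 ± 0.07, camera adjusted p = 9.38e-11, and 0.0411 with an estimated correlation). Of cytokines 10 of 20 were lower (camera adjusted p = 9.54e-06, and adjusted p = 0.16 with an estimated correlation), and the DC maturation genes Cd40 and Il15 had -0.64 ± 0.13 and -0.58 ± 0.11.

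Genes of cholesterol and fatty acid synthesis were higher relative to WT in 16 of 20 cases with LPS (Fasn 0.59 ± 0.10, Dhcr7 0.66 ± 0.14, camera adjusted p = 1.3e-14, and 0.00733 with an estimated correlation). So were 7 of 18 proliferation genes (Bub1 0.70 ± 0.10, Ccnb1 0.80 ± 0.13, camera adjusted p = 3.07e-06, and adjusted p = 0.17 with an estimated correlation). Macrophage markers were lower in 7 of 10 (C1qa -0.88 ± 0.13, camera adjusted p = 1.69e-08, and adjusted p = 0.0982 with an estimated correlation). Among called genes with a given name and a mean of at least 5 CPM, the largest rise was in Commd10 (1.29 ± 0.06, edgeR adjusted p = 2.1e-12). The natriuretic peptide gene Nppc had -1.39 ± 0.17 (2.16e-05). By edgeR 654 genes were higher and 828 lower. With summed pairs edgeR called 2 and 3, Commd10 and Nppc among them, and no member of the lists named here. Without WT LPS replicate 4, 434 were higher. Among the genes called in the LPS interaction, 1261 responded to LPS in the same direction in both genotype labels, and the change was smaller in samples labelled KO for 1203 of them and larger for 58. With zymosan 235 did, 226 with a smaller and 9 with a larger change. The interaction shares its libraries with both responses, so these splits are not independent of the calls.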

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

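The thresholds that single out the values in this part, and the splits of samples, were fixed before the data were examined. The summed pairs and the look at splits that mixed the labels in both conditions were chosen after seeing the data.

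Of 48 tests for a sample far from the other 3 of its group, 2 singled out a value, and chance gives about 1 in 20. Ptgs2 was 1414 CPM in KO zymosan replicate 3 against 1174 to 1193 CPM in the other 3, and Pla2g4a was 53.3 CPM in WT untreated replicate 3 against 50.2 to 50.3 CPM. The response differed between genotype labels by the interaction test for Ptgs1 with zymosan (0.46 ± 0.09), Pla2g4a with zymosan (-0.36 ± 0.08), Ptgs2 with LPS (-0.67 ± 0.15) and Ptgs1 with LPS (0.99 ± 0.09). With summed pairs every one of these gene calls ended, and that of Pla2g4a also ended without KO zymosan replicate 1 or 2. The response to LPS also differed for the XBP1s targets (median -0.25), the NF-κB genes (median -0.24) and the genes of cholesterol and fatty acid synthesis (median 0.32), with camera adjusted p = 0.0315, 0.0411 and 0.00733 under an estimated correlation.

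When the 8 samples of a comparison were divided into 2 groups of 4 in all 35 ways, each fitted without the other samples, only 1 split, the real one, gave as many called genes, in each of the 8 comparisons of 2 groups. The highest other split gave 270 genes for untreated cells of both genotype labels (real 1174) and 108 for zymosan-treated cells (real 2319). Both set replicates 1 and 2 against 3 and 4. The 35 splits treat the 8 samples as interchangeable, although these pairs of replicates resembled each other. With such pairs as the units far fewer splits are possible, so the rank of the real split cannot exclude chance. For the interactions 5 of 100 splits gave as many genes as the real one with zymosan (real 154, highest other 984), and 3 of 100 with LPS (real 1680, highest other 3398). The other splits that reached the real number kept or swapped the genotype label of all 8 samples of 1 condition. They still carry the genotype difference, so these counts cannot decide whether the real number with zymosan arose by chance. Among zymosan splits that mixed the labels in both conditions, looked up afterwards, the highest gave 36 genes.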

How the results depend on the processing

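Whether the 4 replicates of a group are independent is one limit. Summing the counts of replicates 1 and 2 and of 3 and 4, chosen after seeing the data, left 392 results of named genes on their side of the threshold and made 115 weaker, with none reversed, and shared 407 of its 418 calls in untreated cells between genotype labels with the 1411 found before. Crossed sums (1 with 3 or 4), also chosen afterwards and also 2 per group, gave 2746 and 2923 calls there. The number of calls thus depended on which replicates were summed. Each crossed sum holds 1 library of each pair, so the difference between pairs cancels and the spread is understated. Crossed sums therefore cannot decide how much of the loss came from the smaller number of sums. The numbers of higher and lower genes with summed pairs were 2280 and 1979 for WT zymosan against WT LPS, 118 and 300 for untreated cells between genotype labels, 394 and 570 with zymosan, 841 and 1146 with LPS, 0 and 0 for the zymosan interaction and 2 and 3 for the LPS interaction. Replicates 1 and 2 alone, also chosen afterwards, gave 1588 and 1663 between genotype labels in untreated cells, 2509 lower with zymosan, 558 and 648 for the zymosan interaction and 1379 and 1596 for the LPS interaction; replicates 3 and 4 alone gave 74 higher for the zymosan interaction. A model term for the pairs, chosen afterwards, gave 312 and 276 for zymosan and 1081 and 1406 for LPS in the interactions.

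Among the alternatives fixed beforehand, replicate number as a block gave 266 and 240 for the zymosan interaction and 1040 and 1356 for LPS; nested in genotype it gave 292 and 298, and 1073 and 1482. After each group's mean log2 CPM was subtracted, samples of the same number had correlations all over 0.1 only between untreated and zymosan-treated cells (0.151 to 0.247 in WT, 0.125 to 0.205 in KO). Their mean was 0.177 in WT, against 0.148 for all samples of the same pair, and 0.174 against 0.186 in KO; 3 of 4 samples in WT and 1 of 4 in KO correlated best with their own number. The block moved no other count by more than 1.5 times. DESeq2 gave 228 and 196 for the zymosan interaction, and a model of only the groups compared gave 47 lower. Leaving out 1 library at a time gave 69 to 195 higher and 56 to 155 lower for the zymosan interaction, and 434 to 700 higher for LPS. The cause of these changes was not tested.

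Among the named genes and lists, directions turned only for results that had not passed the test. Over all genes, 1 of the 9814 called both with all replicates and with replicates 3 and 4 alone, for WT LPS against untreated, had opposite directions. Ptges2 with zymosan in WT cells was -0.003 in replicates 3 and 4. Xbp1 with LPS in WT cells was 0.007 with DESeq2-type size factors, 0.005 with DESeq2, 0.049 in replicates 3 and 4 and -0.059 to 0.007 when 1 library was left out. In untreated cells between genotype labels Ptgs2 was 0.311 in replicates 3 and 4 and -0.18 to 0.024 without 1 library, Pla2g4a -0.015 in replicates 1 and 2 and down to -0.013 without 1 library, and Ptges2 -0.014 to 0.082 without 1 library. Xbp1 between genotype labels with LPS was 0.004 in replicates 1 and 2, 0.008 in a model of only those groups and up to 0.005 without 1 library, and Ptgs2 in the zymosan interaction was 0.125 in replicates 1 and 2. List tests turned direction with camera adjusted p = 0.984 (stroma markers, WT zymosan against untreated), 0.984 and 0.982 (conventional DC markers between genotype labels, untreated and zymosan) and 0.908 (stroma markers, zymosan interaction) under the replicate block, and with 0.974 (prostanoid synthesis, WT zymosan against untreated) and 0.974 (stroma markers, zymosan in KO) under summed pairs. The cause was not tested.

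An estimated correlation between list genes left 176 list results as they were and made 74 weaker. Scaling by size factors left 498 results of named genes on their side and no filter on low counts 497. Leaving out 1 library at a time kept 4404 such results and made 247 weaker. Depth limits genes of a few counts, such as Il10 in WT untreated cells, to wide intervals. The alternatives planned for a table without counts, a pseudocount and limma without a filter, were not run because the table held counts.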

Other observations

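In WT cells the prostaglandin E receptor gene Ptger1 fell with zymosan (-0.67 ± 0.07) and with LPS (-0.68 ± 0.07), and Ptger4 rose with zymosan (0.44 ± 0.05; n = 4 per group). The leukotriene receptor gene Cysltr2 rose with both (1.31 ± 0.13 and 2.16 ± 0.12). The prostacyclin receptor gene Ptgir was higher in samples labelled KO in untreated cells (0.28 ± 0.04) and with zymosan (0.28 ± 0.04). Among cell type markers, Xcr1 of conventional DCs rose with zymosan and LPS (1.77 ± 0.20 and 2.37 ± 0.19), and Cox6a2, known from plasmacytoid DCs, was higher in samples labelled KO by 1.64 ± 0.28, 1.64 ± 0.31 and 1.88 ± 0.32 in untreated, zymosan-treated and LPS-treated cells. Of the 4 measured markers in that list 2 were higher in untreated cells (camera adjusted p = 0.0187, and adjusted p = 0.17 with an estimated correlation), 2 with zymosan (1 with summed pairs; camera adjusted p = 0.165), and with LPS 1 was higher and 1 lower (median -0.36, camera adjusted p = 0.847).

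Transcripts that the IRE1α RNase is known to degrade were a separate list of 12. Between genotype labels 1 was higher and 2 lower in untreated cells, 3 and 0 with zymosan, and 2 and 6 with LPS (camera adjusted p = 0.634, 0.506 and 0.201). With summed pairs the numbers were 1 and 0, 0 and 0, and 1 and 3. Scara3 was higher with LPS (1.38 ± 0.16) and Pdgfrb lower (-0.93 ± 0.11). In WT cells Tapbp, a member of this list that loads peptides on MHC class I, rose with zymosan (1.91 ± 0.07).

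Of the tests of explanations in this part, those of a repeated library, independent noise and the eosinophil genes were chosen after their results were seen. Those of library size and of the excess on chromosome 6 were chosen before. The patterns themselves, among them that excess, were first seen in these data. The exact test of calls by chromosome was run on each autosome and X, with adjustment over the chromosomes of a comparison.

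Replicates 1 and 2, and replicates 3 and 4, lay closer together than to the other pair in 5 of 6 groups, and on average in WT LPS too (chi-square per gene 5.95 against 9.23 for the next pairing). A single library deposited under both names is excluded, since the smallest chi-square per gene between libraries was 1.91 where counting noise gives 1. The rank correlation of this distance with the difference in library size was 0.0775 over 36 pairs of samples. Each pair was scaled by its median count ratio before the distance was measured, which removes a plain difference in size. The correlation therefore cannot decide whether library size played a part. Sequencing noise independent between samples is excluded too, since it would make each of the 3 ways of pairing 4 replicates as likely to be the closest, and the same one was closest in 6 of 6 groups (exact p = 0.00412). Separate preparations, each sequenced as a pair, remain a hypothesis, because the labels give neither preparation nor animal, and no biological explanation was tested.

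Epx, Prg2 and other eosinophil genes were far lower in samples labelled KO. Fewer cells of the eosinophil lineage in those cultures would lower eosinophil genes neither in the fixed lists nor named before. The 6 measured ones had medians of -2.31, -2.15 and -2.24 in the 3 conditions. In untreated cells these were Ccr3 at -4.49, Gata1 at -2.56, Cebpe at -0.42, Siglecf at -0.17, Ear6 at -2.59 and Ear2 at -2.05. Ear2 and Ear6 belong to the family of near copies of Ear1, whose fall was already known. All 6 were picked after the fall of Epx was seen, so they are no independent check. The medians go with that hypothesis without excluding lower transcription in cells of equal number. Fewer granulocytes of every kind would also lower markers of the other granulocytes. In untreated cells the neutrophil markers had a median of -0.071, and the mast cell and basophil markers -0.291. Neutrophil markers went both ways, from -1.88 for Ly6g to 0.735 for Prtn3, with 4 called lower and 1 higher. Their median therefore shows no fall shared by all of them and cannot exclude fewer neutrophils of some kinds. Reads shared between paralogs are excluded as the sole cause, with a gene at least 4-fold lower in each of 5 unrelated families. Whether the genotype or a difference between cultures lowered them was not tested, because the labels do not separate these.

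Genes called between genotype labels in untreated cells were more frequent on chromosome 6, where Clec4f lies (111 of 699, 15.9%, against 9.71% elsewhere; odds ratio 1.76, 95% interval 1.41 to 2.17; Fisher's exact test, adjusted p = 1.5e-05). They were also more frequent with zymosan (27.8% against 22.0%, odds ratio 1.37, adjusted p = 0.00914), and the difference did not pass with LPS (35.9% against 34.0%, adjusted p = 0.578), by the same exact test. With LPS that test passed for more calls on chromosome 1 (adjusted p = 0.0306) and for fewer on chromosomes 8 and 13 (0.0222 and 0.0369). It also passed within 1 genotype label, for more calls on chromosome 1 between WT LPS and WT untreated (0.028) and fewer on chromosome 7 between KO LPS and KO untreated (0.00498). Chance placement along the genome stays open, as 9.80% of 10000 circular shifts of the calls in untreated cells gave some chromosome as large an excess as chromosome 6. Mean abundance in the model did not remove the excess on chromosome 6 (lower 95% bound of the odds ratio 1.45). That bound treats genes as independent, so it is too narrow if calls cluster along the genome. A stretch of DNA from another strain could neither be shown nor excluded: the window from 40 to 60 Mb chosen on replicates 1 and 2 had an odds ratio of 1.36 in replicates 3 and 4 (95% interval 0.739 to 2.40), and outside it Clec4f (from 83644542) and the pseudogene Spr-ps1 (from 85152621, chosen after its values were seen) lie close together, the latter with 0 counts in all WT samples and 109, 41 and 14 in untreated, zymosan-treated and LPS-treated samples labelled KO.

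As background, a widely used Cre transgene driven by Vav regulatory sequence is known to lie in Commd10, which was 3.24-fold higher in samples labelled KO with LPS; the labels used here name no Cre line, and no test was made.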
